A study of Danio rerio with 24 samples.

How the data were processed

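The series holds 24 RNA sequencing libraries of zebrafish exposed as embryos to PCB126 or to DMSO, 3 in each of 8 groups. The groups are whole embryos at 48 hpf (DMSO, 0.3 nM), whole larvae at 5 dpf (DMSO, 0.3 nM, 1.2 nM) and adult brain at 4 months (DMSO, 0.3 nM, 1.2 nM), taken from the sample titles and characteristics. Per the submitters' extraction notes, total RNA libraries were made with ribosomal RNA depletion, stranded, and read from a single end over 50 bases; RNA of embryos and larvae was purified with a column kit and RNA of brains by another method. The light cycle was 12 h light and 12 h dark; the hour at which brains were taken and whether the numbers of replicates link libraries of different groups are not given in the sources used here.

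The deposited files hold whole-number counts of reads per gene, which the authors made, per the submitters' processing notes, by read quality checks with FastQC, alignment to GRCz10 with STAR and counting with HTSeq; the labels also name edgeR. Versions and the annotation release are not given in the sources used here. The file names state reverse-strand counting in union mode, so reads that fit several genes are not counted. Each file lists 32105 Ensembl gene IDs; 26269 received a symbol from the names tables and 5836 did not. These tables write many zebrafish genes under the symbol of the mammalian ortholog in capitals, such as CYP1A1 for cyp1a, and 1 symbol can stand for several genes, whose Ensembl IDs are then given. The reference annotation provided is of another assembly, so it served for names only, and gene length and base composition were not analysed here.

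Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, a gene being called at an adjusted p under 0.05. Each age was fitted by itself with all its groups; differences between ages and the comparison of DMSO larvae with DMSO embryos used 1 fit of all 24 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM (counts scaled to the TMM-adjusted library size) as mean ± SD of 3 libraries. Log2 fold changes of genes and medians of lists are those of the quasi-likelihood fit. Log2 CPM with a prior count of 2 served for the gene list tests and the correlations between libraries.

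There were 42 gene lists fixed before the data were examined, with 1701 entries of which 1482 matched a gene in the files. A list was tested when at least 5 members were measured, with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists; the same test with a correlation estimated from the data, and fry, were alternatives. Counts over the list alone used a Benjamini-Hochberg adjustment within the list. The genes named were chosen by a rule fixed before the data were examined. It takes every AHR-induced gene, the 12 largest called changes in each direction with a mean log2 CPM of at least 1, a symbol other than a clone name and groups that do not overlap, up to 4 genes per described list by smallest p, and up to 6 genes per dose or interaction comparison by smallest adjusted p. Its exclusion of symbols of capitals followed by digits was applied only to those with at least 5 digits, since the names tables write ortholog symbols in capitals; this was settled before gene values were seen. A few genes that the rule selects are not reported here. At 48 hpf the genes called only with the replicate block, at 5 dpf zgc:173545, and the clock genes of the plot were chosen after their values were seen.

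To see what 3 libraries per group can detect, counts were changed by known folds in simulated data. Genes of low level were not among those changed, and the simulated libraries had no structure by replicate number. The shares are over many genes, so a gene of wide spread can still be missed at a large change, as CYP1A1 was at 1.2 nM in larvae. Of genes changed by 1.5-fold, 2-fold and 4-fold, the test called 43.28%, 88.06% and 100% at 48 hpf, 70.15%, 95.52% and 100% for 0.3 nM at 5 dpf, 62.69%, 94.03% and 100% for 1.2 nM at 5 dpf, 55.22%, 80.6% and 96.97% for 0.3 nM in brain, and 46.27%, 76.12% and 95.45% for 1.2 nM in brain. The raised list was called in each comparison and 0 of 20 unchanged lists were. Simulated genes varied independently, so this cannot show the list calls that arise when real members vary together. The biological coefficient of variation was 0.119 at 48 hpf, 0.0817 at 5 dpf and 0.156 in brain. No 2 libraries of a group were alike to within counting noise; the lowest chi-square per degree of freedom was 2.42.

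Whether libraries with the same replicate number belong together was checked from the data. At 48 hpf the deviations of same-numbered DMSO and exposed libraries from their group means correlated at 0.288 to 0.396, and those of other pairs at -0.174 on average, so the value with the replicate number as a block is given beside the main one. At 5 dpf and in brain, no pair of groups had all its same-numbered libraries above a correlation of 0.1. The 2 exposed groups at 5 dpf came closest, at 0.0742 to 0.269. Their other pairs were at -0.0933 on average and 0.0193 at most. The main test of dose at 5 dpf had no block.

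Alternatives fixed before the data were examined were DESeq2's size factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0's Wald test, quasi-likelihood without robust fitting, the replicate block, a log2 fold change of at least 1, the 50 most abundant genes left out, each library left out in turn, only the 2 groups compared in the fit, and all 24 libraries in 1 fit. Thinning all brain libraries to the smallest total, and leaving brain DMSO replicate 2 or 3 out of the list tests, were added after the data were seen. Where libraries were split in other ways, all 10 splits of 6 libraries were fitted, and 25 were drawn for each comparison of ages. Part of the agreement of doses that share DMSO libraries was estimated from 20 simulations of unchanged groups. The comparison of adult brain with larvae or embryos as such was not analysed here, since tissue and age differ together.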

Results

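RNA was sequenced from zebrafish that had been exposed as embryos to PCB126 (a dioxin-like polychlorinated biphenyl that activates the aryl hydrocarbon receptor, AHR) or to the solvent DMSO alone. There were 24 libraries, 3 in each of 8 groups. Whole embryos were collected at 48 hours post-fertilization (hpf) after DMSO or 0.3 nM PCB126. Whole larvae were collected at 5 days post-fertilization (dpf), and adult brains at 4 months after rearing in clean water, each after DMSO, 0.3 nM or 1.2 nM PCB126. The series text describes the 3 libraries of a group as biological replicates. The question was which genes differ while the compound or its early effects are present, and which differ in the adult brain long after exposure.

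Every file listed reads for 32105 Ensembl genes. At 48 hpf the totals per library were 16169218 to 17750955 reads for DMSO and 12974658 to 16922713 for 0.3 nM. At 5 dpf they were 12480715 to 14932821 for DMSO, 15564323 to 18668231 for 0.3 nM and 16831991 to 20662041 for 1.2 nM. In adult brain they were 19498374 to 23022236 for DMSO, 13097392 to 15911244 for 0.3 nM and 14394116 to 18043641 for 1.2 nM, so that all 3 DMSO brain libraries were deeper than every exposed one.

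At 48 hpf, 0.3 nM PCB126 raised CYP1A1 and cyp1c1, which encode cytochrome P450 enzymes switched on by the AHR. CYP1A1 (ENSDARG00000098315) rose 12.6-fold, from 15.8 ± 4.53 to 199 ± 48.8 CPM (counts scaled to library size; mean ± SD, n = 3 in each group), a log2 fold change of 3.65 with a standard error (SE) of 0.26. The related cyp1c1 (ENSDARG00000101195) rose 4.60-fold, from 11.3 ± 1.22 to 51.9 ± 13.5 CPM (SE 0.19 on the log2 scale). The adjusted p was 0.00239 for CYP1A1 and 0.00272 for cyp1c1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). They were the 2 genes called among 20265 tested, both higher; 525 genes had an unadjusted p under 0.05, where chance alone gives 1013.25.

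Of 9 measured members of the list of AHR-induced genes, 2 rose over all genes tested and 4 when adjusted over the list alone, the others being cyp1c2 and CYP1B1. The cyp1c2 level was 9.22 ± 1.04 against 3.68 ± 1.12 CPM (log2 fold change 1.32, SE 0.20, adjusted p = 0.205), and CYP1B1 was at 12.6 ± 1.05 against 7.37 ± 0.658 CPM (0.78, SE 0.13, adjusted p = 0.363). The log2 fold changes of tiparp (-0.01), FOXQ1 (0.00), foxq1b (0.34), NQO1 (0.06) and gstp1.2 (0.01) all had an adjusted p of 1. Too few reads fell on ahrra, ahrrb, gstp1.1 and wfikkn1 for a test, with at most 9, 23, 9 and 8 in any library. As a set these genes ranked above the rest (camera, adjusted p = 7.73e-08), and the adjusted p was 0.82 with an estimated correlation.

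Other gene groups shifted by small amounts at 48 hpf, with no member called. The glutamatergic synapse list (45 genes, median log2 fold change 0.17, camera adjusted p = 5.94e-07) included SLC17A7 at 0.47 and GRIA3 at 0.38, the voltage-gated channels (63 genes, 0.14, adjusted p = 1.59e-06) cacna1db at 0.63, and the photoreceptor list (29 genes, 0.20, adjusted p = 0.000659) saga at 0.61. Lists with negative medians were the erythroid genes (16 genes, -0.28, adjusted p = 1.14e-07), with the globin gene hbae5 at 3.55 ± 0.282 against 5.61 ± 1.39 CPM, and the cell cycle list (59 genes, -0.13, adjusted p = 7.73e-08), with aurka at -0.30. Skeletal muscle (61 genes, -0.14, adjusted p = 7.57e-05), with ckmb at -0.38, and ribosomal proteins (78 genes, -0.10, adjusted p = 7.58e-05), with RPL6 at -0.23, were also lower. For these 7 lists the adjusted p was between 0.82 and 0.933 with an estimated correlation.

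At 48 hpf same-numbered DMSO and exposed libraries deviated together, and with the replicate number as a block 27 genes were called, 10 higher and 17 lower, with 1475 at an unadjusted p under 0.05. All 4 CYP1 genes then passed: CYP1A1 (log2 fold change 3.66, adjusted p = 9.61e-13), cyp1c1 (2.18, 3.48e-08), cyp1c2 (1.34, 0.00306) and CYP1B1 (0.78, 0.0179). The UDP-glucuronosyltransferases ugt1b1 (0.61, adjusted p = 0.0179) and ugt1b5 (0.54, 0.0338), PKHD1L1 (0.55, 0.0263) and agt, the angiotensinogen gene (0.47, 0.0496), also rose. Those that fell included ponzr4 (-1.28, adjusted p = 0.00132), ponzr3 (-0.91, 0.0179), the embryonic globin genes hbae1.2 (-0.58, 0.0179) and hbbe3 (-0.58, 0.0195), fkbp15a (-0.65, 0.0477), DDIT4 (-0.47, 0.0477) and PYGM, the muscle glycogen phosphorylase gene (-0.44, 0.0477). Without the block, 1 gene was called with DMSO replicate 2 left out and 4 with exposed replicate 3 left out.

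At 5 dpf, larvae exposed to 0.3 nM differed from DMSO larvae in no gene by edgeR's quasi-likelihood test (0 of 21719, smallest adjusted p = 0.477). CYP1A1 stood at 102 ± 52.8 against 28.7 ± 1.49 CPM (n = 3 each), a log2 fold change of 1.82 with SE 0.51 and an adjusted p of 0.995. The cyp1c1 level was 29.6 ± 6.60 against 19.8 ± 0.727 CPM (log2 fold change 0.58, SE 0.36). Log2 fold changes were 0.22 for CYP1B1, 0.13 for cyp1c2, 1.66 (SE 1.08) for the AHR repressor gene ahrra, -0.55 for ahrrb, 0.09 for tiparp, 0.34 for FOXQ1, 0.20 for foxq1b, -0.05 for NQO1, 0.06 for gstp1.1 and 0.08 for gstp1.2, while wfikkn1 had too few reads. None of these 12 genes passed when adjusted over the list alone either.

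The AHR-induced list had a median log2 fold change of 0.17 in these larvae (camera adjusted p = 0.0183, and adjusted p = 0.827 with an estimated correlation). Ribosomal proteins (78 genes, median 0.14, adjusted p = 2.45e-20; RPS28 at 0.22), oxidative phosphorylation (81 genes, 0.08, 5.34e-06; NDUFB8 at 0.20), liver genes (49 genes, 0.10, 0.000104; fabp10a at 0.30) and skeletal muscle (62 genes, 0.07, 0.00022; ckma at 0.18) had positive medians, and photoreceptors (44 genes, -0.07, 0.00644; ARR3 at -0.28) a negative one. No member of these 5 lists was called, and for each the adjusted p was 0.827 with an estimated correlation. There were 1034 genes at an unadjusted p under 0.05, where chance gives 1085.95. DESeq2 called 2 genes, edgeR without robust fitting 1, a fit of these groups alone 1, and the main test without DMSO replicate 3 called 2.

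Larvae exposed to 1.2 nM PCB126 had higher cyp1c2 and higher levels of the receptor gene ahr2. The cyp1c2 level rose 3.06-fold, from 3.22 ± 0.540 to 9.87 ± 3.1 CPM (log2 fold change 1.61, SE 0.21, adjusted p = 0.0341, n = 3 each, edgeR quasi-likelihood test). The ahr2 level rose from 130 ± 10.6 to 185 ± 14.8 CPM (log2 fold change 0.51, SE 0.08, adjusted p = 0.0393). Of 21719 genes 10 were called, 7 higher and 3 lower, with 1472 at an unadjusted p under 0.05. The other 5 that rose were mamdc2b (1.33, SE 0.21, adjusted p = 0.0393), the forkhead factor gene foxf2a (0.87, SE 0.12, 0.0341), cyp2aa12 (0.78, SE 0.12, 0.0383), and a pair of genes of the circadian clock list, rorcb (0.51, SE 0.08, 0.0392) and nfil3-5 (0.45, SE 0.08, 0.0484). Those that fell were mrc1b, a scavenger receptor gene of lymphatic and venous endothelium (-0.53, SE 0.09, adjusted p = 0.0484), plvapb, which encodes a protein of endothelial fenestrae (-0.51, SE 0.08, 0.0383), and zgc:173545.

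CYP1A1 had the largest fitted change of the AHR-induced genes at 1.2 nM, 23.9-fold, but varied widely between the 3 exposed libraries. It stood at 685 ± 341 against 28.7 ± 1.49 CPM (log2 fold change 4.58, SE 0.55, adjusted p = 0.0933). The same held for cyp1c1 at 110 ± 47.9 against 19.8 ± 0.727 CPM (2.48, SE 0.35, adjusted p = 0.136) and CYP1B1 at 20.9 ± 10.7 against 5.77 ± 0.234 CPM (1.84, SE 0.39, 0.43). Of 12 measured members 1 rose over all genes and 8 when adjusted over the list alone. The members not yet described include some that passed over the list alone. They were ahrra (3.32, adjusted p = 0.544), ahrrb (0.35, 0.858), tiparp (0.29, 0.298), FOXQ1 (0.91, 0.336), foxq1b (0.48, 0.43), NQO1 (0.08), gstp1.1 (0.25) and gstp1.2 (0.08). The list's median log2 fold change was 0.70 (camera adjusted p = 1.85e-14, and adjusted p = 0.413 with an estimated correlation).

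**Figure D1:**
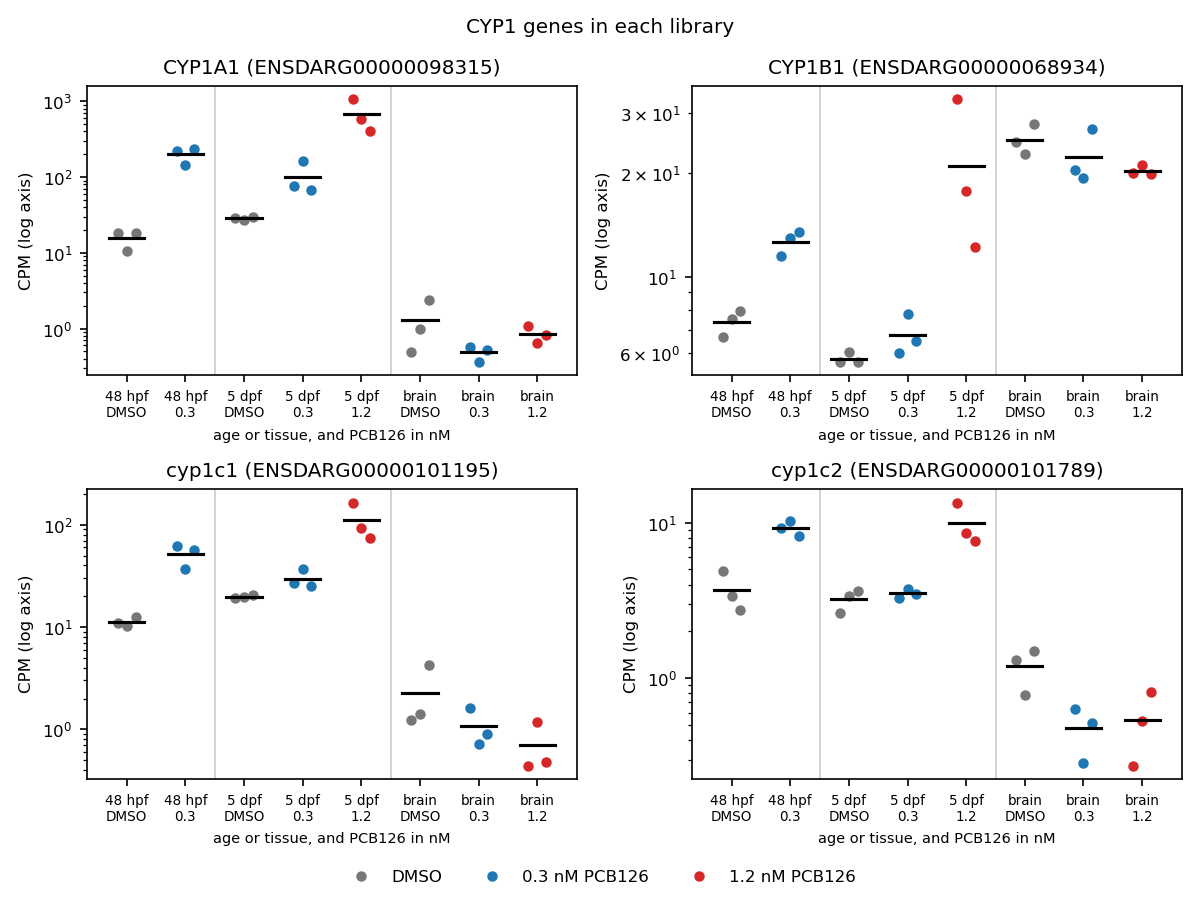
CPM of CYP1A1, CYP1B1, cyp1c1 and cyp1c2 in each of the 24 libraries on a log axis, by age or tissue and PCB126 concentration; points are libraries and black lines the means of 3. CYP1A1 was at 15.8 CPM on average in DMSO embryos and 199 in exposed ones at 48 hpf, and at 28.7, 102 and 685 CPM in larvae at 5 dpf after DMSO, 0.3 nM and 1.2 nM.

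Among other lists at 1.2 nM in larvae, the circadian clock genes had 2 of 36 members higher, rorcb and nfil3-5, and 8 higher and 1 lower when adjusted over the list alone (median 0.07, camera adjusted p = 0.000174, and adjusted p = 0.752 with an estimated correlation). The endothelium list had 1 of 29 lower, plvapb, with vwf at 0.86 (adjusted p = 0.0588) and stab1 at -0.34 (0.246); its median was 0.02 and its camera adjusted p 0.849. In the list of AHR signalling components, 1 of 11 rose, ahr2, and HSP90AA1 was at -0.43 (adjusted p = 0.203); the list's median was -0.01 while its mean was 0.01 and the test pointed up (adjusted p = 0.779). Liver genes had a median of 0.13 (49 genes, 0 called, 3 higher over the list alone, adjusted p = 3.39e-07), with fabp10a at 331 ± 33.5 against 250 ± 19.7 CPM, and exocrine pancreas genes 0.24 (26 genes, 0 called, adjusted p = 0.000174), with ela2 at 0.38. For these lists the adjusted p was 0.489 and 0.882 with an estimated correlation.

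Ribosomal proteins at 1.2 nM had a median of 0.10 (78 genes, camera adjusted p = 4.34e-11; RPS28 at 0.18). Heat shock genes had -0.20 (20 genes, adjusted p = 0.00859), with hsp90aa1.1 at -0.64. The gonad and germ cell list had a median of -0.17 and a mean of -0.52 (21 genes, adjusted p = 0.00217), with the egg coat gene zp3a.1 at 0.436 ± 0.142 against 1.63 ± 0.516 CPM (adjusted p = 0.0754) and the oocyte gene buc at 0.225 ± 0.0974 against 1.24 ± 0.501 CPM (0.0828). None of their members was called; 3 germ cell genes were lower over the list alone. For these lists the adjusted p was 0.866, 0.752 and 0.413 with an estimated correlation. All 10 calls at this dose were lost without DMSO replicate 1, without DMSO replicate 2 and in a fit of these 2 groups alone, which each called 0 genes; DESeq2 called 56, and 3, 4 and 30 were called without exposed replicate 1, 2 and 3.

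Comparing 1.2 with 0.3 nM in larvae tests the dose itself. Deviations of same-numbered libraries correlated at 0.0742 to 0.269 between these groups, and the main test had no replicate block. The higher dose had more rorcb (log2 difference 0.64, SE 0.08, adjusted p = 0.0103, edgeR quasi-likelihood test) and cyp1c2 (1.48, SE 0.20, 0.0247). It had less plvapb (-0.59, SE 0.08, adjusted p = 0.0103), ftr69 (-3.41, SE 0.53, 0.0368) and HSP90AA1 (-0.63, SE 0.09, 0.0368). These 5 were the genes called of 21719 tested, with 993 at an unadjusted p under 0.05, and nlrc11 came next (0.99, adjusted p = 0.16). Over the AHR-induced list alone, 7 of 12 were higher at the higher dose: cyp1c2 (adjusted p over the list alone = 4.09e-05), CYP1A1 (2.76, 0.00493), cyp1c1 (1.90, 0.00493), CYP1B1 (1.62, 0.00976), tiparp (0.0248), ahrrb (0.0309) and FOXQ1 (0.0309). The list's median was 0.74 (camera adjusted p = 1.46e-13, and adjusted p = 0.263 with an estimated correlation).

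Heat shock genes (20 genes, median -0.19, camera adjusted p = 0.000248; dnajb1a at -0.19), cell cycle genes (59 genes, -0.13, 4.02e-06; CCNB1 at -0.41) and immediate early genes (16 genes, -0.16, 0.000205; egr1 at -0.27) had negative medians at 1.2 against 0.3 nM in larvae, with none of their members called. For these lists the adjusted p was 0.565, 0.782 and 0.463 with an estimated correlation. The count of 5 genes became 1, 3 and 2 without 0.3 nM replicate 1, 2 and 3, 9 without 1.2 nM replicate 3, 1 in a fit of these groups alone and 12 with DESeq2.

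In adult brain, 4 months after exposure, many genes differed from DMSO at 0.3 nM, most by less than a doubling. Nuclear genes of oxidative phosphorylation fell in 67 of 81 cases and ribosomal protein genes in 24 of 78, while 16 of 46 genes of glutamatergic synapses, 23 of 60 of voltage-gated channels and 27 of 66 of chromatin rose. No list passed camera with an estimated correlation (0 of 41). Of 19548 genes, 1529 were higher and 1154 lower (2683 in all, 5906 at an unadjusted p under 0.05, edgeR quasi-likelihood test). The median size of the called changes was 0.485 on the log2 scale, and 204 genes changed by at least 1, 57 higher and 147 lower. The fit of all 24 libraries called 4120 genes and turned the balance, with 1865 higher and 2255 lower. The groups did not overlap in 32.6% of genes, where chance gives 10%.

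Among the largest rises at 0.3 nM were rorcb, an orphan nuclear receptor gene of the clock (from 40.8 ± 6.52 to 110 ± 12.4 CPM, log2 fold change 1.43, SE 0.15, adjusted p = 0.00293, n = 3 each), and nfil3-5, related to the clock-controlled repressor NFIL3 (from 65.5 ± 10.7 to 143 ± 14.8 CPM, 1.12, SE 0.18, 0.00877). NDST1, a heparan sulfate modifying enzyme gene, rose from 20.2 ± 1.47 to 57.5 ± 15.8 CPM (1.51, SE 0.24, 0.00975), and pclob, for a large protein of the presynaptic active zone, from 366 ± 100.6 to 815 ± 95.0 CPM (1.15, SE 0.18, 0.00797). Others were PLCB2 (1.32, adjusted p = 0.0334), NYAP2 (1.23, 0.0043), the postsynaptic scaffold gene DLGAP2 (1.19, 0.019), the transcription factor gene pou2f2b (1.18, 0.00588), IGSF9B, for an adhesion molecule of inhibitory synapses (1.13, 0.0043), FAM222A (1.12, 0.014) and the clustered protocadherins pcdh2aa15 (1.15, 0.0126) and pcdh1g22 (1.09, 0.0258). Members of these clusters resemble one another, and reads that fit several of them are not counted.

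The globin gene named HBE1 (ENSDARG00000069734) fell to 0.285 ± 0.152 CPM in the 0.3 nM brains from 12.06 ± 4.66 in DMSO (log2 fold change -5.40, SE 0.55, adjusted p = 0.0043). Other genes carry the same symbol, and reads that fit several of them are not counted. DIO2, the deiodinase that makes active thyroid hormone, went from 102 ± 7.98 to 33.8 ± 16.8 CPM (-1.60, SE 0.33, 0.0239) and SLC5A5, the iodide transporter, from 7.07 ± 0.702 to 2.18 ± 1.01 CPM (-1.68, SE 0.26, 0.0067). The thyroid axis list as a whole had 2 higher and 2 lower of 14. COCH (-4.24, adjusted p = 0.0378) and the cartilage collagen gene COL10A1 (-3.50, 0.0445) fell from 51.6 ± 56.1 and 22.7 ± 21.3 CPM, wide spreads among the DMSO brains. Others were mst1ra (-2.22, adjusted p = 0.00521), the clotting factor gene F10 (-1.81, 0.0123), HSD17B3 (-1.80, 0.00857), a Vault RNA (-1.73, 0.0185), SERPINH1 (-1.56, 0.0293), chad (-1.55, 0.0189) and serpinf1 (-1.52, 0.0454). Of the genes in this and the previous paragraph of text, those lost without DMSO replicate 3 were pcdh1g22, DIO2, SERPINH1 and serpinf1, and without DMSO replicate 1 these, COCH, COL10A1, PLCB2 and the Vault RNA. Calls for pcdh1g22, COCH, COL10A1, PLCB2, the Vault RNA, SERPINH1, serpinf1, chad and DLGAP2 were lost without exposed replicate 2 and without exposed replicate 3. FAM222A was also lost without the first of these, DIO2 without the second, COCH and COL10A1 without exposed replicate 1, and pcdh1g22 without DMSO replicate 2.

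Of 81 measured oxidative phosphorylation genes, 67 fell and 0 rose at 0.3 nM, and 78 fell when adjusted over the list alone (median log2 fold change -0.49, camera adjusted p = 8.1e-28, and adjusted p = 0.426 with an estimated correlation). COX7A2 went from 81.9 ± 2.29 to 44.5 ± 6.25 CPM (-0.88, SE 0.09, adjusted p = 0.00293), with atp5mf (-0.63, 0.0046), cox6c (-0.63, 0.00558) and NDUFA6 (-0.73, 0.00588). Of 78 ribosomal protein genes 24 fell, 68 over the list alone (median -0.38, camera adjusted p = 7.25e-17, and adjusted p = 0.494 with an estimated correlation). Examples were RPL31 (-0.45, 0.0143) and RPL38 (-0.36, 0.0158). Heat shock and chaperone genes fell in 8 of 19 (11 over the list alone, median -0.46, adjusted p = 3.86e-06, and adjusted p = 0.22 with an estimated correlation). Members included HSPA8 (-0.67, 0.00599) and the mitochondrial chaperone HSPD1 (-0.46, 0.00876). Antioxidant genes fell in 8 of 23 (11 over the list alone, median -0.26, adjusted p = 0.000222, and adjusted p = 0.426 with an estimated correlation). Among them were SOD1 (-0.46, 0.00756) and GPX4 (-0.51, 0.00729).

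Glutamatergic synapse genes rose in 16 of 46 cases, 23 over the list alone, and 0 fell (median 0.28, camera adjusted p = 7.49e-09, and adjusted p = 0.426 with an estimated correlation). The postsynaptic scaffold gene shank1 went from 35.8 ± 7.29 to 66.7 ± 5.79 CPM (0.90, SE 0.13, adjusted p = 0.0067), with syngap1b (0.66, 0.00857) and shank3b (0.57, 0.0116). Of 60 voltage-gated channel genes 23 rose (32 higher and 1 lower over the list alone, median 0.31, adjusted p = 5.2e-09, and adjusted p = 0.426 with an estimated correlation). Examples were the calcium channel genes cacna1da (0.61, 0.0067) and CACNA1C (0.74, 0.00746). Inhibitory synapse genes rose in 9 of 38 (11 higher and 1 lower over the list alone, median 0.11, adjusted p = 0.00296, and adjusted p = 0.621 with an estimated correlation). Members included nlgn2a (0.58, 0.00797) and gabrb4 (0.68, 0.00994). The summed level of this list did not rise, at 6728 to 6810 CPM against 5961 to 7283 in DMSO, where replicate 3 was lowest. Of 66 genes of DNA methylation and chromatin 27 rose (33 over the list alone, median 0.28, adjusted p = 1.56e-10, and adjusted p = 0.247 with an estimated correlation). Among them were the histone methyltransferase genes setd1a (0.89, 0.0043), kmt2bb (0.67, 0.00498) and DOT1L (0.71, 0.00518).

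Glial and immune genes fell in smaller numbers at 0.3 nM. Myelin genes fell in 6 of 23 (11 over the list alone, median -0.43, camera adjusted p = 0.000222, and adjusted p = 0.426 with an estimated correlation). Examples were myelin basic protein, mbpa, at -0.84 (adjusted p = 0.0091) and mag at -0.44 (0.0427). Microglia and macrophage genes fell in 5 of 27 (median -0.37, adjusted p = 0.000202, and adjusted p = 0.494 with an estimated correlation). Members included the receptor csf1ra at -0.50 (0.00831) and the complement gene c1qb at -1.19 (0.0193). Lipid and glucose metabolism had 3 genes higher and 14 lower of 56 (4 and 19 over the list alone, median -0.26, adjusted p = 0.000356, and adjusted p = 0.22 with an estimated correlation). Among them were IRS1 (0.45, 0.00857) and igf2b (-0.76, 0.00994). Erythroid genes fell in 4 of 14 (median -0.60, adjusted p = 0.000222, and adjusted p = 0.426 with an estimated correlation), including hbaa2, at 0.138 ± 0.144 against 6.71 ± 3.25 CPM (-5.52, SE 0.86, 0.0091), and nt5c2l1 (-1.11, 0.00831).

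The clock list had 8 members higher and 3 lower of 36 at 0.3 nM (10 and 5 over the list alone, median 0.08, camera adjusted p = 0.0999); CLOCK (0.61, adjusted p = 0.00718) and bmal2 (0.65, 0.00832), which encode activators, rose and ciarta, a repressor gene, fell (-0.64, 0.00746). No immediate early gene of 16 was called (0, median 0.29, adjusted p = 0.0999; egr1 at 0.72, 0.141). The thyroid axis list had 2 higher and 2 lower of 14; THRB (0.24, adjusted p = 0.03) and SLCO1C1 (0.30, 0.0284) rose, and the list's median was 0.04 while its mean was -0.29 and the test pointed down (0.828). Of the AHR-induced genes measured in brain 1 was called, NQO1, which fell from 6.39 ± 1.66 to 2.97 ± 0.504 CPM (-1.10, SE 0.26, adjusted p = 0.0213). CYP1A1 was at 0.484 against 1.29 CPM (-1.40, 0.118), cyp1c1 at -1.08 (0.22), cyp1c2 at -1.30 (0.0882), CYP1B1 at -0.17 (0.39), tiparp at 0.17 (0.314), foxq1b at -0.01 and gstp1.2 at -0.20; ahrra, ahrrb, FOXQ1, gstp1.1 and wfikkn1 had too few reads.

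Markers of other tissues varied among the brain libraries. Summed over the skeletal muscle list, DMSO replicate 3 had 4653 CPM and the other 8 brain libraries 660 to 911; over cartilage and bone it had 3309 against 676 to 1184, and over pituitary hormones 554 against 192 to 275, while DMSO replicate 2 had 267 CPM of photoreceptor genes against 15.6 to 78.3. Liver and epidermis markers were higher in all 3 DMSO brains than in every exposed one: 547 to 875 CPM against 270 to 416 at 0.3 nM and 364 to 462 at 1.2 nM for liver, and 753 to 1070 against 470 to 628 and 504 to 597 for epidermis. Of 15 measured liver genes 3 fell at 0.3 nM (median -0.69, camera adjusted p = 0.00426, and adjusted p = 0.247 with an estimated correlation) and 2 at 1.2 nM (median -0.68, 0.00138, and adjusted p = 0.444 with an estimated correlation). At 0.3 nM, 2 of 51 skeletal muscle genes rose, the calcium release channels RYR1 (0.46, adjusted p = 0.0147) and RYR3 (0.36, 0.0376), which neurons also express, while the set ranked low (camera adjusted p = 0.000331, and adjusted p = 0.685 with an estimated correlation; 0.13 without DMSO replicate 3). Cartilage and bone had 2 higher, as SOX6 (0.41, 0.021), and 7 lower of 47, as PHEX (-1.03, 0.0226; median -0.67, camera adjusted p = 0.000119, and adjusted p = 0.494 with an estimated correlation). The signal recognition particle RNA rn7sl1 took 8.22% ± 1.31 of reads in DMSO brains, 5.75% ± 0.868 at 0.3 nM and 5.49% ± 0.577 at 1.2 nM (two-sided exact permutation p = 0.1 for each dose, the smallest that 3 against 3 allow).

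**Figure D2:**
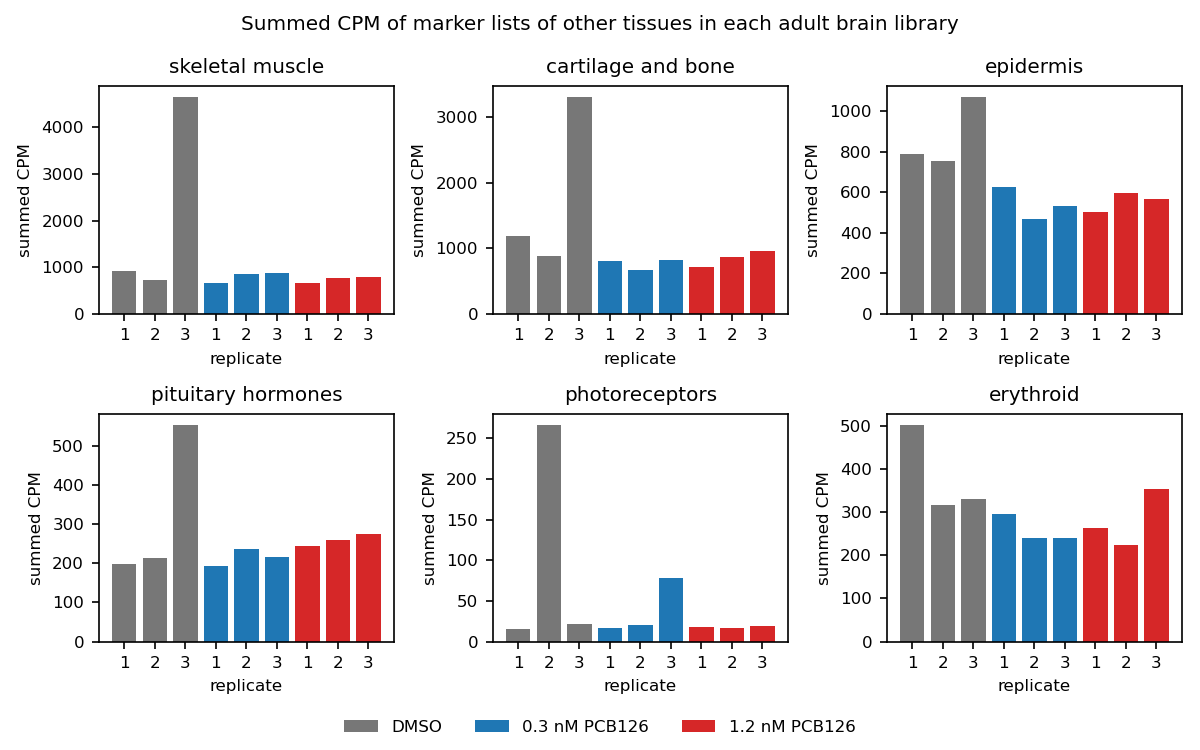
Summed CPM of 6 marker lists in each of the 9 adult brain libraries; bars are single libraries, coloured by treatment. DMSO replicate 3 stands out for skeletal muscle (4653 CPM) and cartilage and bone (3309 CPM), and DMSO replicate 2 for photoreceptors (267 CPM).

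Leaving out 1 library moved the count of 2683 to 1427 without DMSO replicate 1, 1418 without DMSO replicate 3, 960 without exposed replicate 2 and 971 without exposed replicate 3, and a fit of these 2 groups alone called 1310. Without DMSO replicate 3 the numbers of lower genes were 45 for oxidative phosphorylation, 4 for ribosomal proteins, 1 for myelin and 1 for microglia, and those of higher genes 8 for glutamatergic synapse, 15 for channels and 22 for chromatin.

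At 1.2 nM, ribosomal protein genes fell in 67 of 78 cases in adult brain, the clock repressor ciarta fell 3.53-fold, and 5 of 16 immediate early genes rose. No list passed camera with an estimated correlation (0 of 41). Of 19548 genes 1112 were higher and 657 lower (1769 in all, 5445 at an unadjusted p under 0.05, edgeR quasi-likelihood test), with a median size of 0.474 on the log2 scale and 98 genes changed by at least 1, 14 higher and 84 lower. The fit of all 24 libraries called 1705 higher and 1730 lower. The groups did not overlap in 35.9% of genes, where chance gives 10%.

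ADGRB1, for an adhesion receptor of synapses, rose from 117 ± 5.64 to 257 ± 23.8 CPM (log2 fold change 1.13, SE 0.10, adjusted p = 0.00266, n = 3 each), rorcb to 103 ± 16.2 CPM (1.34, SE 0.15, 0.00723) and nfil3-5 to 150 ± 35.0 CPM (1.20, SE 0.18, 0.018). Activity-regulated transcription factor genes rose too: NPAS4 from 6.03 ± 1.26 to 16.1 ± 6.77 CPM (1.41, SE 0.34, adjusted p = 0.0396), FOSL2 from 43.5 ± 7.57 to 85.7 ± 9.83 CPM (0.98, SE 0.13, 0.013) and ATF3 (1.18, 0.0219). Others were PLCB2 (1.37, adjusted p = 0.0386), RNF19B (1.07, 0.0121), FAM222A (1.07, 0.0279), the potassium channel gene KCNK13 (1.05, 0.0234), MAP3K9 (0.98, 0.0136) and NYAP2 (0.98, 0.0139).

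ciarta fell from 25.2 ± 1.65 to 7.13 ± 0.555 CPM (log2 fold change -1.82, SE 0.11, adjusted p = 5.18e-05), and NR1D1, for the clock repressor REV-ERB alpha, from 14.6 ± 2.83 to 3.54 ± 1.61 CPM (-2.05, SE 0.36, 0.0226). ANGPTL4, for an inhibitor of lipoprotein lipase, fell from 34.1 ± 5.72 to 5.99 ± 1.14 CPM (-2.51, SE 0.29, 0.0126), as did the fatty acid transport enzyme CPT1B (-2.09, SE 0.28, 0.0121) and nmrk2 (-1.70, 0.0161). The lipid and glucose metabolism list had 1 higher and 4 lower of 56 (median -0.13, camera adjusted p = 0.0445, and adjusted p = 0.453 with an estimated correlation). Others that fell were the muscle sodium channel gene scn4ab (-3.37, adjusted p = 0.0446), the keratins krt15 (-2.48, 0.0488) and krt91 (-1.83, 0.0405), the collagen-processing genes pcolcea (-1.90, 0.0274) and P4HA1 (-1.49, 0.0139), and RUNX3 (-1.82, 0.048). Of the genes in this and the previous paragraph, rorcb, ADGRB1 and ciarta stayed called whichever library was left out. CPT1B was lost without exposed replicate 1, and all the others without exposed replicate 3. Without exposed replicate 2, nfil3-5, NPAS4, ATF3, PLCB2, FAM222A, KCNK13, NYAP2, NR1D1, nmrk2, scn4ab, krt15, krt91, pcolcea, P4HA1 and RUNX3 were lost. Without exposed replicate 1 the same were lost except nfil3-5, NPAS4, ATF3 and nmrk2, and MAP3K9 and ANGPTL4 besides. Without DMSO replicate 3 the calls for NPAS4, PLCB2, FAM222A, KCNK13, scn4ab, krt15, NR1D1, pcolcea, krt91 and RUNX3 were lost, and without DMSO replicate 1 those for ATF3, NPAS4, PLCB2, scn4ab, krt15, krt91, pcolcea and RUNX3. Without DMSO replicate 2 only NPAS4 was lost.

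Of 36 clock genes 6 rose and 15 fell at 1.2 nM, 10 and 19 over the list alone (median -0.30, camera adjusted p = 0.0619, and adjusted p = 0.525 with an estimated correlation). The nuclear receptor gene NR1D2 (ENSDARG00000009594) went from 351 ± 11.7 to 192 ± 12.14 CPM (-0.87, SE 0.09, adjusted p = 0.00426), and CLOCK (ENSDARG00000011703) rose (0.68, SE 0.10, 0.0132). Immediate early genes rose in 5 of 16 cases, 7 over the list alone (median 0.92, adjusted p = 1.36e-06, and adjusted p = 0.453 with an estimated correlation). Examples were NR4A3 (0.75, 0.0182) and EGR3 (0.62, 0.0229). Summed over the immediate early list, libraries held 413 to 861 CPM at 1.2 nM and 268 to 515 after DMSO, so the groups overlapped. Without DMSO replicate 3, 4 clock genes rose and 12 fell, and 4 immediate early genes rose. Without exposed replicate 3 only 13 genes of any kind were called, so many of these calls were lost there.

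**Figure D3:**
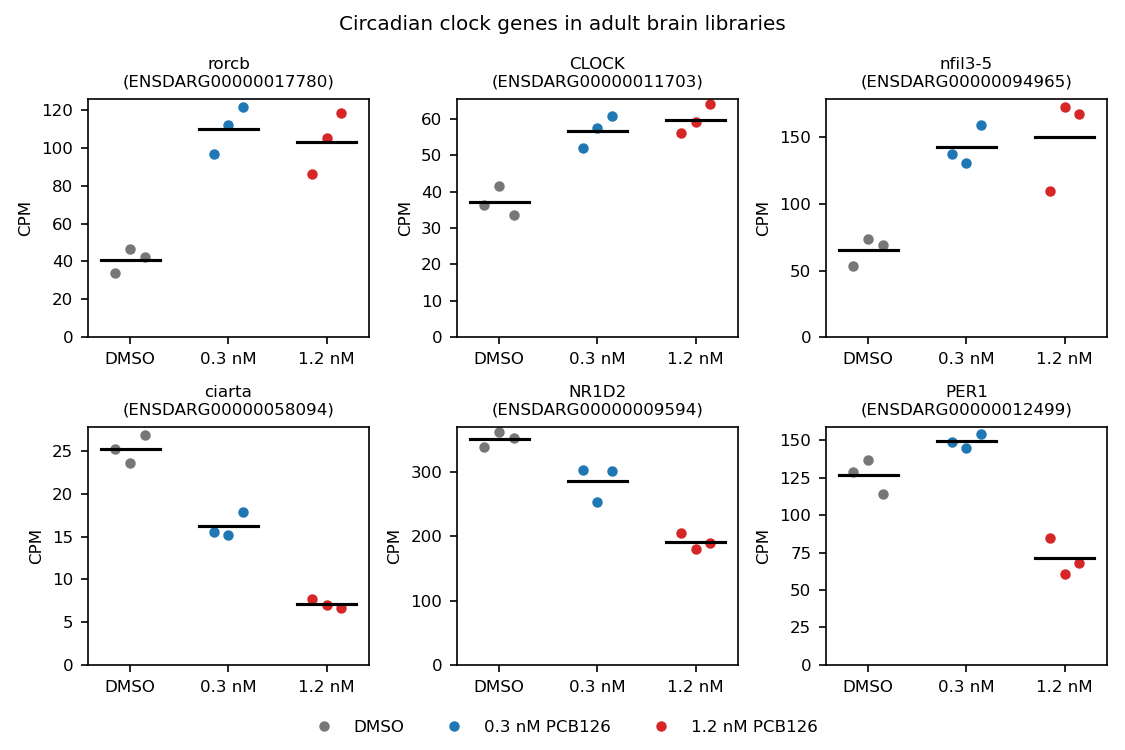
CPM of 6 genes of the clock list in the 9 adult brain libraries, with axes starting at 0; points are libraries and black lines the means of 3 per treatment. ciarta averaged 25.2 CPM after DMSO, 16.2 after 0.3 nM and 7.13 after 1.2 nM, and rorcb 40.8, 110 and 103 CPM.

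Ribosomal protein genes fell in 67 of 78 at 1.2 nM, 78 over the list alone (median -0.54, camera adjusted p = 2.37e-28, and adjusted p = 0.453 with an estimated correlation). Members included RPLP1 (-0.62, SE 0.10, adjusted p = 0.018) and RPL34 (-0.53, SE 0.09, 0.0182). Oxidative phosphorylation genes fell in 21 of 81, 48 over the list alone (median -0.31, adjusted p = 1.27e-13, and adjusted p = 0.488 with an estimated correlation). Among them were COX7A2 (-0.51, 0.0195) and NDUFB4 (-0.42, 0.0202). Glutamatergic synapse genes rose in 13 of 46 (24 higher and 1 lower over the list alone, median 0.26, adjusted p = 3.55e-10, and adjusted p = 0.453 with an estimated correlation). Examples were the glutamate receptor gene GRM5 (0.84, 0.018) and shank1 (0.70, 0.0213). Channel genes had 20 higher and 1 lower of 60 (31 and 2 over the list alone, median 0.29, adjusted p = 1.33e-10, and adjusted p = 0.453 with an estimated correlation). The potassium channel gene KCNA4 was at 0.61 (0.0235). Inhibitory synapse genes rose in 7 of 38 (15 higher and 1 lower over the list alone, median 0.25, adjusted p = 5.43e-05, and adjusted p = 0.488 with an estimated correlation). The receptor subunit gene GABRA4 was at 0.60 (0.0308). Chromatin genes rose in 22 of 66 (35 over the list alone, median 0.25, adjusted p = 6.59e-11, and adjusted p = 0.444 with an estimated correlation). Examples were TET2, for a DNA demethylase (0.49, 0.0139), and KMT2D (0.65, 0.0195).

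Microglia and macrophage genes fell in 7 of 27 at 1.2 nM (12 over the list alone, median -0.64, camera adjusted p = 4.94e-08, and adjusted p = 0.453 with an estimated correlation). Members included csf1ra (-0.57, adjusted p = 0.0139) and cd74a (-0.68, 0.0328). Radial glia genes had 1 higher and 7 lower of 30 (1 and 8 over the list alone, median -0.34, adjusted p = 0.00375, and adjusted p = 0.453 with an estimated correlation). Among them were VIM (-0.54, 0.0226) and FABP7 (-0.45, 0.0387). Epidermis markers, high in the DMSO brains at 753 to 1070 CPM, fell in 5 of 21 (12 over the list alone, median -0.74, adjusted p = 8.39e-06, and adjusted p = 0.453 with an estimated correlation). The keratin gene krt5 was at -1.17 (0.0385). Skeletal muscle had 1 higher of 51, RYR1 (0.46, adjusted p = 0.0265), while the set ranked low (3.84e-07, and adjusted p = 0.525 with an estimated correlation), and cartilage and bone had 1 higher and 3 lower of 47 (median -0.58, 0.00219, and adjusted p = 0.525 with an estimated correlation). Members included SOX5 (0.41, 0.0357) and COL9A1 (-1.62, 0.0265); DMSO replicate 3 held 4653 and 3309 CPM of these lists. No AHR-induced gene was called: CYP1A1 was at -0.59 (adjusted p = 0.489), CYP1B1 at -0.30 (0.151), cyp1c1 at -1.70 (0.0885), cyp1c2 at -1.17 (0.125), tiparp at 0.31 (0.0808), foxq1b at -0.66 (0.264), NQO1 at -0.30 (0.467) and gstp1.2 at -0.17 (0.539).

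The count of 1769 fell to 462 without DMSO replicate 1, 530 without DMSO replicate 3, and 38, 44 and 13 without exposed replicates 1, 2 and 3, and was 2698 with DESeq2. Of the 1769, 35, 42 and 10 were still called without exposed replicates 1, 2 and 3. Without DMSO replicate 3 the numbers of lower genes were 12 for ribosomal proteins, 4 for oxidative phosphorylation, 1 for microglia and 1 for epidermis, and those of higher genes 4 for glutamatergic synapse, 8 for channels, 3 for inhibitory synapse and 14 for chromatin.

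**Figure D4:**
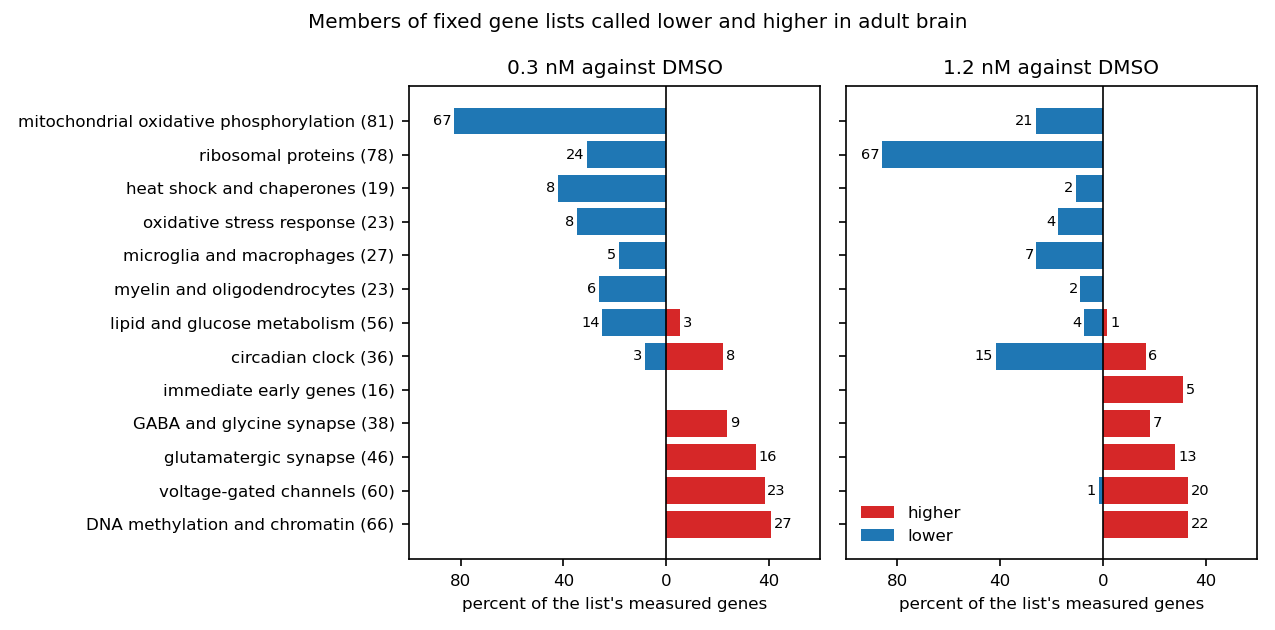
Share of the measured members of 13 fixed gene lists called lower (left of 0) and higher (right of 0) in adult brain at 0.3 nM and 1.2 nM against DMSO, with the number of genes at each bar and the number measured in parentheses. Oxidative phosphorylation had 67 of 81 genes lower at 0.3 nM and 21 at 1.2 nM, ribosomal proteins 24 and 67 of 78, and glutamatergic synapse 16 and 13 of 46 higher.

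Between the doses in adult brain, ciarta (log2 difference -1.18, SE 0.11, adjusted p = 0.00281, edgeR quasi-likelihood test) and PER1 (ENSDARG00000012499; -1.07, SE 0.12, 0.0106) were lower at 1.2 than at 0.3 nM. HBE1 was higher (5.44, SE 0.55, adjusted p = 0.0154), since its level was near 0 at 0.3 nM alone. Also called were dap1b (-1.54, SE 0.12, adjusted p = 0.00074), lonrf1 (-0.84, SE 0.10, 0.0154) and SPART (0.99, SE 0.12, 0.0154). Of 19548 genes 19 were called, 10 higher and 9 lower, with 1885 at an unadjusted p under 0.05. Clock genes were lower in 4 of 36, 17 over the list alone with 1 higher (median -0.27, camera adjusted p = 1.24e-09, and adjusted p = 0.423 with an estimated correlation). Among them were PER3 (-0.80, 0.0275) and NR1D2 (-0.58, 0.0475). Immediate early genes were higher in 1 of 16, JUN (0.72, 0.0483), 4 over the list alone (median 0.68, adjusted p = 4.71e-06, and adjusted p = 0.568 with an estimated correlation).

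No member was called in other lists between the brain doses, ribosomal proteins included (0 of 78, median -0.16, camera adjusted p = 2.2e-06, and adjusted p = 0.828 with an estimated correlation). Oxidative phosphorylation (median 0.19, 8 of 81 higher over the list alone, camera adjusted p = 2.67e-15; cycsb at 0.59, 0.0813), neuropeptides (median 0.26, 4 of 30 higher over the list alone, 6.25e-05; penka at 0.49, 0.113) and heat shock genes (median 0.25, 4 of 19 higher and 1 lower over the list alone, 0.00192; HSPD1 at 0.38, 0.164) had positive medians, and cell cycle genes a negative one (median -0.37, 3 of 58 lower over the list alone, 3.49e-11; MCM3 at -0.65, 0.166). For these lists the adjusted p was 0.568, 0.423, 0.563 and 0.568 with an estimated correlation. The count of 19 became 8, 30 and 4 without 0.3 nM replicates 1, 2 and 3, 2 and 4 without 1.2 nM replicates 2 and 3, and 160 with DESeq2.

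**Figure D5:**
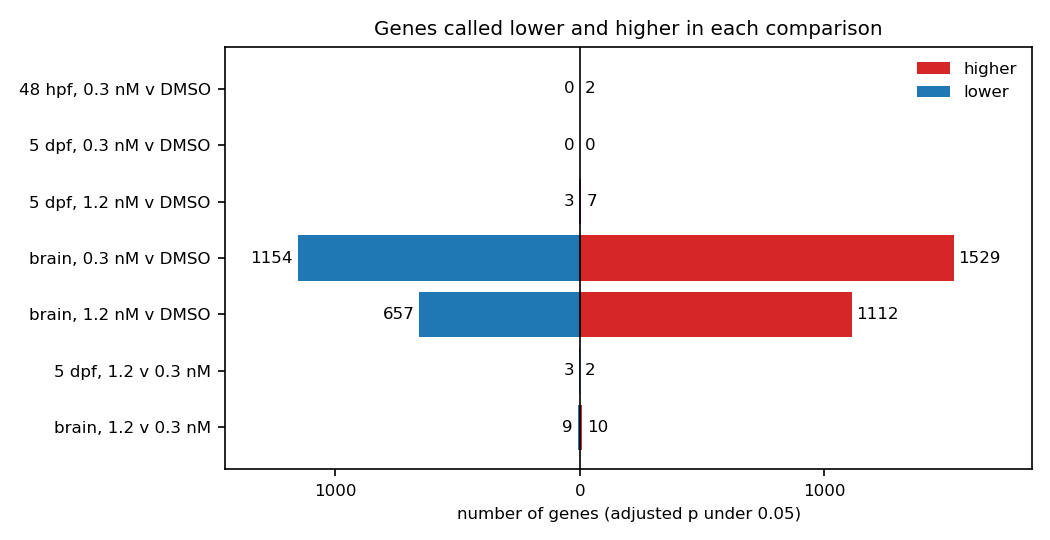
Numbers of genes called lower (left of 0) and higher (right of 0) in each comparison between PCB126 and DMSO and between doses. The counts were 2 and 0 higher for 0.3 nM at 48 hpf and 5 dpf, 7 higher and 3 lower for 1.2 nM at 5 dpf, and in brain 1529 and 1154 for 0.3 nM and 1112 and 657 for 1.2 nM.

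The doses shared 1166 genes called in the same direction against DMSO in adult brain, 823 higher and 343 lower, and 2 were called in opposite directions. Independent lists of these sizes would share 87.0 and 38.8. With 2 simulated unchanged groups against shared simulated DMSO libraries, 0 genes were shared on average over 20 simulations. Unchanged groups give almost no calls, so this 0 was nearly fixed in advance and sets no level for lists of these sizes. Across genes, which are not independent replicates, the fold changes correlated at 0.756, against 0.496 in the simulations, with a covariance of 0.132 against 0.0317. The simulations drew each gene independently, so deviations that many genes share in the real DMSO libraries are absent from them. Part of the excess may thus come from the shared DMSO libraries, and 3 controls are too few to give each dose its own 2. At 5 dpf no gene was called at 0.3 nM (0 by edgeR, 1034 at an unadjusted p under 0.05, 2 with DESeq2), so none could be shared between the doses; the fold changes had a correlation of 0.598 against 0.534 and a covariance of 0.0147 against 0.0117.

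Between ages, 3 genes were called at 1.2 nM in the same direction in larvae and adult brain. They were rorcb (0.51 in larvae and 1.34 in brain) and nfil3-5 (0.45 and 1.20), both higher, where chance gives 0.409 (Fisher's exact test across genes, two-sided p = 0.0589), and mrc1b (-0.53 and -0.77), lower, where chance gives 0.0684 (p = 0.0672). At 0.3 nM, 0 genes were called at 5 dpf by edgeR (1034 at an unadjusted p under 0.05, 2 with DESeq2) and 2 at 48 hpf, so almost none could be shared between ages. Across genes the correlation of fold changes was -0.0876 between 48 hpf and 5 dpf at 0.3 nM, 0.113 between 48 hpf and brain at 0.3 nM, -0.0915 between 5 dpf and brain at 0.3 nM and -0.0190 between them at 1.2 nM.

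Whether an effect differed between ages was tested on the difference of log2 fold changes in the fit of all 24 libraries. The main fit had no replicate block, although same-numbered libraries deviated together at 48 hpf. Between 5 dpf and 48 hpf at 0.3 nM no gene differed (edgeR quasi-likelihood test, 0 of 22545, 820 at an unadjusted p under 0.05 where chance gives 1127.25, 0 also with DESeq2). Over the AHR-induced list alone 4 of 12 were lower at 5 dpf: CYP1A1 (difference -1.83, adjusted p over the list alone = 0.0156), cyp1c1 (-1.62, 0.0156), cyp1c2 (-1.19, 0.0156) and ahrrb (-1.85, 0.0458), each with an adjusted p of 1 over all genes. The list ranked low (camera adjusted p = 0.00785) and the ribosomal proteins high (3.98e-16; RPL8 at 0.39), with an adjusted p of 0.965 with an estimated correlation for both. The genes with the smallest adjusted p included GALNT17 (-0.75, 0.819), mt-atp8 (-0.95, 0.819), ELMOD2 (-0.53, 1) and PGK2 (0.41, 1); dre-let-7e and xirp1 were near 0 at 48 hpf, so no fold change is given for them. Without 48 hpf exposed replicate 3, 1 gene differed.

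Adult brain and larvae differ in tissue as well as age. The fit of all 24 libraries also shares 1 spread per gene across ages, although the biological coefficient of variation was 0.156 in brain and 0.0817 at 5 dpf. The p-values of the previous paragraph, this one, the next one and the comparison of the DMSO groups rest on that shared spread. At 0.3 nM the response differed between them in 1288 genes, 606 with a higher and 682 with a lower log2 fold change in brain (of 22545, 5089 at an unadjusted p under 0.05, edgeR quasi-likelihood test). Differences were 1.54 for rorcb (SE 0.18, adjusted p = 0.000294), 1.55 for NYAP2 (SE 0.21, 0.000731), 0.92 for pcdh11 (SE 0.13, 0.00104), -1.37 for IVNS1ABP (SE 0.17, 0.000294), -0.86 for the polyamine oxidase gene SMOX (SE 0.11, 0.000562), -2.14 for mst1ra (SE 0.28, 0.000607) and -1.05 for NQO1 (0.0288). Oxidative phosphorylation genes were lower in 61 of 81 (77 over the list alone, median -0.59, camera adjusted p = 3.84e-35, and adjusted p = 0.214 with an estimated correlation). COX7A2 differed by -1.06 (adjusted p = 0.00171). Ribosomal proteins were lower in 18 of 78 (76 over the list alone, median -0.54, 6.51e-24, and adjusted p = 0.349 with an estimated correlation). RPL31 differed by -0.65 (0.0124). Channels had 12 higher and 1 lower of 63 (20 and 1 over the list alone, median 0.34, 2.69e-08, and adjusted p = 0.291 with an estimated correlation). HCN4, a pacemaker channel gene, differed by 1.11 (0.00721). Chromatin genes had 18 higher of 68 (26 higher and 1 lower over the list alone, median 0.30, 8.95e-11, and adjusted p = 0.214 with an estimated correlation). TET2 differed by 0.60 (0.00375). With DESeq2's size factors the split was 736 to 548. The count was 656 and 659 without larval DMSO replicates 1 and 2, 540 and 809 without larval exposed replicates 1 and 2, 2135 and 628 without brain DMSO replicates 2 and 3, and 1937, 619 and 772 without brain exposed replicates 1, 2 and 3.

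At 1.2 nM the response differed between brain and larvae in 336 genes, 114 higher and 222 lower in brain (4392 at an unadjusted p under 0.05). The CYP1 genes had lower log2 fold changes in brain: CYP1A1 by -5.17 (SE 0.91, adjusted p = 0.0143), cyp1c1 by -4.19 (SE 0.72, 0.0122), cyp1c2 by -2.82 (SE 0.46, 0.00335) and CYP1B1 by -2.16 (SE 0.33, 0.00321), 4 of 12 listed genes (5 over the list alone, median -1.11, camera adjusted p = 7.98e-07, and adjusted p = 0.21 with an estimated correlation). None of these 4 was called against DMSO in brain at this dose, and CYP1A1 had a low level there, so the size of its difference is uncertain. Other differences were -1.84 for ciarta (SE 0.15, adjusted p = 2.52e-07), -1.03 for NR1D2 (SE 0.11, 4.34e-05), -1.76 for PER1 (ENSDARG00000056885; SE 0.22, 0.000281), -2.48 for ANGPTL4 (SE 0.27, 5.58e-05), -2.05 for CPT1B (SE 0.24, 5.58e-05) and -1.02 for the heat shock factor gene HSF2 (SE 0.14, 0.000506). Clock genes had 2 higher and 11 lower of 36 (4 and 18 over the list alone, median -0.38, 2.36e-05, and adjusted p = 0.21 with an estimated correlation), immediate early genes 3 higher of 16 (8 over the list alone, median 0.97, 5.19e-09, and adjusted p = 0.21 with an estimated correlation). JUN differed by 0.60 (0.029). Ribosomal proteins had 23 lower of 78 (78 over the list alone, median -0.66, 5.58e-38, and adjusted p = 0.258 with an estimated correlation). RPS15 differed by -0.82 (0.0254). The count was 75, 63 and 205 without larval DMSO replicates 1, 2 and 3, 67, 103 and 193 without the larval exposed ones, 1112 and 117 without brain DMSO replicates 2 and 3, and 105, 176 and 145 without the brain exposed ones.

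Between the DMSO groups, larvae at 5 dpf differed from embryos at 48 hpf in 14350 of 22545 genes, 7282 higher and 7068 lower (edgeR quasi-likelihood test, 15059 at an unadjusted p under 0.05). Digestive genes rose, among them 24 of 26 exocrine pancreas genes (2 fell; camera adjusted p = 1.08e-15, and adjusted p = 0.0229 with an estimated correlation). Trypsinogen, prss1, went from 1.63 ± 0.514 to 1293 ± 133 CPM (adjusted p = 2.6e-16). Of 33 intestine genes 28 rose (4 fell; 5.09e-11, and adjusted p = 0.0121 with an estimated correlation). The cholesterol transporter gene NPC1L1 went from 0.426 ± 0.096 to 70.7 ± 5.21 CPM (9.34e-20). Photoreceptor genes rose in 40 of 44 (2 fell; 8.05e-11, and adjusted p = 0.315 with an estimated correlation). The green opsin gene opn1mw1 went from 0.166 ± 0.135 to 496 ± 38.6 CPM. Glutamatergic synapse genes rose in 43 of 47 (median 1.68, 1.08e-15, and adjusted p = 0.0792 with an estimated correlation). GRIN1, an NMDA receptor gene, was at 2.86. Monoamine genes rose in 32 of 42 (2 fell; median 1.20, 7.82e-06, and adjusted p = 0.0121 with an estimated correlation). DDC, for the enzyme that makes dopamine and serotonin, was at 3.54. Pigment cell genes fell in 15 of 17 (2 rose; median -2.23, 1.12e-06, and adjusted p = 0.0121 with an estimated correlation). OCA2, a melanosome gene, was at -2.23. Cell cycle genes fell in 46 of 60 (median -1.29, 5.09e-11, and adjusted p = 0.315 with an estimated correlation). The mitotic kinase gene plk1 was at -2.03.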

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

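The tests of sampling hour, thinning and other tissue for the clock genes were chosen after the result was seen; the differences between brain and larvae and the splits of the libraries were planned. Each result below differs between adult brain and whole larvae by a test of the difference of the log2 fold changes (edgeR quasi-likelihood, Benjamini-Hochberg); tissue and age differ together in it.

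At 0.3 nM, 1288 genes differed in their response between brain and larvae. In 1 of 25 drawn splits, the real one, as many genes were called, and the highest of the others gave 1149. That split kept the real brain groups and regrouped the larvae. As far as this 1 split shows, the count of 1288 rests mainly on the brain groups and depends little on the larval ones. The other 23 broke up the brain groups and gave at most 3, so the splits do not decide whether chance among the larvae gives the difference. The named differences were 1.54 for rorcb (adjusted p = 0.000294), -1.37 for IVNS1ABP (0.000294), -0.86 for SMOX (0.000562), -2.14 for mst1ra (0.000607), 1.55 for NYAP2 (0.000731), 0.92 for pcdh11 (0.00104) and -1.05 for NQO1 (0.0288).

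At 1.2 nM, 336 genes differed. Again the real split alone (1 of 25) gave as many, with 312 as the highest other, from a split that kept the real brain groups, and at most 3 from the rest. Here too the count rested mainly on the brain groups, and the same question about the larvae stays open. The named differences were -2.48 for ANGPTL4 (adjusted p = 5.58e-05), -2.05 for CPT1B (5.58e-05), -1.02 for HSF2 (0.000506), and, among AHR-induced genes, -5.17 for CYP1A1 (0.0143), -2.16 for CYP1B1 (0.00321), -4.19 for cyp1c1 (0.0122) and -2.82 for cyp1c2 (0.00335). Of the clock genes, ciarta differed by -1.84 (2.52e-07), NR1D2 by -1.03 (4.34e-05) and PER1 (ENSDARG00000056885) by -1.76 (0.000281).

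The clock genes were weighed further. In brain the median of the clock activators (bmal, clock and npas2 genes) lay above 0. The median of repressors and output genes (per, nr1d, dbp, tef, hlf and ciart genes) lay below 0. Other clock list members, such as the cry, ror, nfil3 and bhlhe genes, were in neither set. The first median minus the second was 0.953 at 1.2 nM (0.437 over 6 activators, -0.516 over 17 repressor and output genes). It was 0.632 at 0.3 nM (0.454 and -0.178), while in larvae it was 0.0689 at 1.2 nM and -0.169 at 0.3 nM. Of the 17 genes, 0 were called higher and 10 lower at 1.2 nM, and 1 higher and 3 lower at 0.3 nM. A difference of the hour at which groups of brains were taken would give such opposite signs of the medians, and it remains a candidate explanation. Depth does not account for the pattern, since 22 clock genes were called at 1.2 nM after thinning to the smallest total against 21 before. Without DMSO replicate 3, 93.24% of the median change of those 21 was left. They were called with that library in, and a call favours genes on which replicates agree, so this does not exclude its other tissue as a cause. Without DMSO replicate 2, 8 clock genes rose and 14 fell at 1.2 nM, against 6 and 15 with it, and 9 rose and 3 fell at 0.3 nM, against 8 and 3. The liver and epidermis markers higher in all 3 DMSO brains were not tested as a cause and stay open. A lasting shift of the clock by exposure would give the same values and was not tested, because sampling hours are not given in the sources used here.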

How the results depend on the processing

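The thinning of brain libraries was chosen after the result was seen; the other tests were planned. The count of genes called at 48 hpf (2) became 27 with the replicate block, 4 with DESeq2 and 1 with all 24 libraries in 1 fit; for 0.3 nM at 5 dpf (0 by edgeR, 1034 at an unadjusted p under 0.05) it became 1 without robust fitting, 2 with DESeq2 and 1 with only the 2 groups compared. For 1.2 nM at 5 dpf (10) it was 3 at a log2 fold change of at least 1, 35 with no filter, 5 at 1 CPM, 27 with the block, 56 with DESeq2 and 0 with only the 2 groups. In brain, 2683 at 0.3 nM (1529 higher, 1154 lower) became 204 at a log2 fold change of at least 1, 1310 with only the 2 groups and 4120 (1865 and 2255) with all libraries, and 1769 (1112 and 657) at 1.2 nM became 98, 1027 with the block, 2698 with DESeq2 and 3435 (1705 and 1730) with all libraries; thinned, they were 2597 and 1644. Between doses, 5 at 5 dpf became 2 at a log2 fold change of at least 1, 12 with DESeq2, 1 with only the 2 groups and 3 with all libraries; 19 in brain became 10, 29 with no filter, 11 without robust fitting, 4 with the block, 160 with DESeq2 and 176 with all libraries. Differences between brain and larvae were 279 at 0.3 nM and 120 at 1.2 nM for at least 1 on the log2 scale, and 1990 and 1054 with DESeq2; those between DMSO larvae and embryos numbered 6017 of at least 1. Leaving out 1 library gave 1 to 4 at 48 hpf, 0 to 2 and 0 to 30 for 0.3 and 1.2 nM at 5 dpf, 960 to 3057 and 13 to 2263 in brain, 1 to 9 and 2 to 30 between doses at 5 dpf and in brain, 0 to 1 between 5 dpf and 48 hpf, 540 to 2135 and 63 to 1112 between brain and larvae, and 13064 to 13777 between DMSO ages. Camera's 181 list calls became 5 with an estimated correlation and 90 with fry. Shared calls at a log2 fold change of at least 1 were 32 between brain doses and 0 between 5 dpf and brain at 1.2 nM. A fold threshold lowers a count by construction; otherwise the cause was not tested. Of 6931 values of 444 named results under alternatives, 6236 kept their side of the threshold, 601 fell below it and 94 passed it. Among genes called in either fit 0 reversed, while a change of sign in genes called in neither was not counted. Changes of 1.5-fold were recovered in 43.28% of simulated cases at 48 hpf, which limits what its counts can hold. The share was 40.3% between the doses in brain. For the difference between brain and larvae at 0.3 nM it was 16.42%, and 56.72% for changes of 2-fold, so those counts are limited too.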

Other observations

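The tests of depth, other tissue and a gradient for the brain counts, and of blood and other copies for HBE1, were chosen after the result was seen; the gene calls, list tests and splits were planned. Larvae differed from embryos after DMSO in more ways than digestive and visual genes. Circadian genes rose in 27 of 36 cases and fell in 7 (median log2 fold change 1.63, camera adjusted p = 1.37e-07, and adjusted p = 0.0509 with an estimated correlation), with dbpa, a clock output gene, at 3.00 (adjusted p = 2.82e-18). Cholesterol synthesis and uptake rose in 20 of 30 and fell in 1 (median 1.17, 1.93e-05, and adjusted p = 0.326 with an estimated correlation), with the receptor gene ldlra at 3.55 (3.08e-16). Lipid and glucose metabolism rose in 45 of 66 and fell in 5 (median 0.70, 0.000114, and adjusted p = 0.0188 with an estimated correlation), with the fatty acid receptor gene CD36 at 5.33 (8.06e-19). Radial glia and progenitor genes fell in 21 of 30 and rose in 4 (median -0.75, 7.55e-05, and adjusted p = 0.107 with an estimated correlation), with neurog1 at -3.54, and ribosomal proteins fell in 76 of 78 (median -0.55, 1.21e-09, and adjusted p = 0.536 with an estimated correlation), with RPS26 at -0.79 (3.05e-06).

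The number of genes called between exposed and DMSO brains was weighed as a pattern. Deeper DMSO libraries do not account for it, since the counts after thinning were 92.93% or more of those before. Of the genes called, 2362 of 2683 and 1484 of 1769 were called again. Without DMSO replicate 3, 87.85% of the median change of the called genes was left at 0.3 nM (quartiles 79.9 to 97.4). At 1.2 nM 86.29% was left (78.2 to 94.8), although the counts fell to 1418 and 530. The genes were called with that library in, and a call favours genes on which replicates agree. The test therefore leans to such a result and does not exclude its other tissue as a source of part of the calls. The liver and epidermis markers higher in all 3 DMSO brains were not tested as a cause and stay open. A gradient that also varies among replicates was not decided: the correlation across genes furthest from 0, between a 0.3 nM library's deviation and the change at 1.2 nM, was -0.230, against 0.183 and 0.0544 in the other libraries. Many synapse, channel and chromatin genes rose, and many ribosomal protein and oxidative phosphorylation genes fell. By general knowledge the first have mostly long transcripts and the others short ones. A bias by transcript length or RNA quality would thus bear on all these lists. It was not tested, because the annotation at hand is of another assembly (GRCz12tu) than the counts (GRCz10), and it stays open beside a lasting effect of exposure.

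HBE1 (ENSDARG00000069734) was near 0 in each 0.3 nM brain, at 0.128, 0.431 and 0.297 CPM, against 17.1, 7.89 and 11.2 after DMSO and 7.69, 12.4 and 17.2 after 1.2 nM; hbaa2 (ENSDARG00000069735) was near 0 in the same libraries. Less blood does not account for it, since the median of the other erythroid genes was -0.60 (median absolute deviation 0.409) against -5.40. Reads given to another copy stay open: the sum of the other HBE1 copies differed by -164.9 CPM at 0.3 nM (SE 81.94), a spread too wide to show a gain of the 11.78 CPM lost. A sequence variant or haplotype carried by the fish of that group could give such a loss; no sequence was at hand to test it, and a lasting effect of exposure also stays open.

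Other splits of the libraries were fitted for the remaining counts. With 10 splits of 6 libraries they are too few for a share under 0.05. The real split of the brain libraries gave 2683 genes at 0.3 nM against 1 in the highest of the others, and 1769 at 1.2 nM against 2, as large in 1 split each. For the dose in brain it gave 19 against 4, for 1.2 nM at 5 dpf 10 against 1, for the dose at 5 dpf 5 against 1 and for DMSO larvae against embryos 14350 against 0, each in 1 split. For 0.3 nM at 5 dpf all 10 splits gave 0 genes by edgeR's test (1034 at an unadjusted p under 0.05 in the real one, 2 genes with DESeq2), which leaves nothing to test. At 48 hpf 3 splits gave at least the real 2; the highest, 69, set DMSO replicate 2 with exposed replicates 1 and 2 against the rest, which points to a structure of the samples by replicate number, and among the 4 splits that part all same-numbered pairs the highest other gave 0. For the difference between 5 dpf and 48 hpf all 25 drawn splits gave 0 genes by edgeR's test, the real one included (820 at an unadjusted p under 0.05, 0 with DESeq2). No split can give fewer than 0, so this decides nothing.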
